A study of Homo sapiens with 36 samples.

How the data were processed

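Transcript tags were measured in 36 libraries of 2 human melanoma lines, 501mel and IGR37, grown per the labels in RPMI with 10% FBS. Each line had 6 groups of 3 libraries: DMSO, an SCD inhibitor (SCDi, labelled A939372, 1 uM), control siRNAs siCTR#1 and siCTR#2, and SCD siRNAs siSCD#1 and siSCD#2. Per the labels' protocols, siRNAs were used at 20 nM for 48 hours, RNA was purified with RNeasy, and QuantSeq Forward libraries of 3' transcript ends were made. Per the submitters' processing notes, reads were aligned to hg38 with STAR and normalised with edgeR, with no versions given.

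The authors deposited 2 tables of log2 values, normalised separately. The first held 24 libraries (DMSO, SCDi, siCTR#2 and siSCD#2 of both lines), with 13364 genes, 66 spike-ins and 1 Mitf-FLAG sequence. The second held 12 libraries (siCTR#1 and siSCD#1), with 13066 genes and 60 spike-ins. The tables had 12896 genes in common. The deposited log2 values behaved as log2 CPM, library-scaled read counts, with a prior count of 0.25 and library scaling factors of 0.920 to 1.06 in the first table and 0.916 to 1.07 in the second. Under that form every value gave a whole number of reads, within a distance of 0.000423 and 0.000299 reads. Recovered gene reads per library were 4078450 to 6685898 and 2402788 to 7483010, with 2.43 to 7.21% and 3.76 to 5.71% of reads on spike-ins. At this depth a gene with 0 reads in a library could have a true level of up to 0.385 to 1.18 CPM, depending on the library. Spike-ins and the Mitf-FLAG sequence stayed out of the gene tests. Genes carried only symbols, of which 12593 and 12338 matched a name in GENCODE 29, which supplied identifiers, hg38 coordinates and 3' untranslated regions.

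Each table was fitted on the deposited log2 values with limma (lmFit, contrasts.fit and eBayes with a variance trend), with 1 coefficient per group and all libraries of the table sharing the spread. Tests were made only within a table, were two-sided, and were adjusted by Benjamini-Hochberg (BH) over all genes of the table. A gene passed at an adjusted p under 0.05. The comparisons were SCDi against DMSO, siSCD#1 against siCTR#1 and siSCD#2 against siCTR#2 in each line, the difference of each effect between the lines (IGR37 minus 501mel), and IGR37 against 501mel under DMSO. A filter asking for a log2 value above 0 in 3 libraries removed 0 genes, so dropping it changed no number. Replicate numbers were not used as blocks, because they paired too poorly: only 5 of 17 pairs of equal number had residual correlations above 0.1. The labels number the IGR37 siSCD#2 libraries 1, 2 and 13 and the table's columns 1, 2 and 3, so the last column was given to the group and not to a numbered library.

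The 25 gene lists were fixed before the data were examined. They were fatty acid synthesis and desaturation, cholesterol synthesis and uptake, LXR targets, lipid droplet and fatty acid oxidation, the PERK-ATF4 amino acid response, the IRE1-XBP1 and ATF6 response, MITF and pigment cell differentiation, dedifferentiated and invasive melanoma, NF-kB and inflammatory genes, and the interferon response. The others were DNA replication and S phase, G2 and mitosis, p53 targets and cell death, NRF2 and oxidative stress, hypoxia and glycolysis, oxidative phosphorylation, cytosolic ribosomal proteins, autophagy and lysosome, cytosolic heat shock, MAPK pathway output, YAP-TEAD targets, mitochondrially encoded transcripts, and markers of epithelial, fibroblast, and blood and endothelial cells. Lists with at least 5 measured members (22 of 25) were tested with limma camera, with a preset correlation between genes of 0.01 and BH adjustment over the lists of a comparison. Members past the threshold were counted both with p adjusted over all genes and with p adjusted over the list alone.

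Named genes followed a rule also fixed before the data were examined: SCD, MITF, ATF4 and AXL always. The 6 largest rises and 6 largest falls per comparison were added, among genes with adjusted p under 0.05, treated libraries all on the same side of all controls, and a mean level at or above the median of tested genes. Symbols of pseudogenes, antisense and unnamed or small RNA genes were left out of these. Each list past the threshold gave its 3 members with the smallest adjusted p, and every other list at most 1. For differences between lines the 5 largest in each direction were taken, and for shared changes 8 in each direction. Some genes that the rule names are not used here. A fold against a group with 0 reads was given as "at least" (3 counts over the group), and a ratio against 1 to 3 reads with its counting interval. The "at least" values take the reads of the other group as exact, so they are not strict lower bounds where those reads are few.

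Alternatives were fits of only the groups compared, no variance trend, a stricter filter (log2 value above 2 in 3 libraries, keeping 11388 and 11149 genes), a pseudocount of 1, quantile normalisation, centring on the median, replicate blocks, and leaving out each library. For lists they were an estimated correlation between genes and the fry test. Added after results were seen were limma voom on the recovered reads, library weights, and a fit without the 3 IGR37 siSCD#2 libraries. The fit was tested on simulated reads with planted changes, drawn from group levels of the recovered reads. The spread of each gene was averaged over the groups, so the draws lacked the wider spread of the IGR37 siSCD#2 libraries. The fit recovered 82 to 100% of 2-fold changes, 26 to 62% of 1.5-fold changes and 0 to 26% of 1.25-fold changes, depending on the comparison. Unchanged genes made up 1.7 to 13.6% of its calls. A planted 1.5-fold rise of a list was called in 10 of 10 runs, with 3 of 210 other lists called. Genes were drawn independently, so these rates do not show how camera behaves where genes of a list move together. Every 7-base word in 3' untranslated regions was also scored by the mean log2 fold change of genes with and without it. No library was a copy of another. Mitochondrially encoded transcripts were absent from the tables, with 0 of 13 measured.

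R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.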

Results

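SCD puts the first double bond into saturated fatty acids. The question was which genes change in 501mel and IGR37 melanoma cells when the enzyme is inhibited or its mRNA is lowered, and whether MITF, the regulator of the pigment cell lineage, changes with it. Changes below are log2 fold changes ± SE from limma, with BH adjusted p and n = 3 libraries per group. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

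SCD mRNA (ENSG00000099194.5, chromosome 10, 100347124 to 100364834, plus strand) fell with both siRNAs in both lines. In 501mel its mean log2 CPM ± SD was 9.79 ± 0.03 with siCTR#1 and 6.94 ± 0.11 with siSCD#1, a change of -2.85 ± 0.07 (adjusted p = 3.63e-13). With siSCD#2 it was 5.03 ± 0.07 against 9.36 ± 0.13 with siCTR#2 (-4.33 ± 0.16, adjusted p = 1.54e-16). In IGR37 the levels were 7.43 ± 0.09 against 10.09 ± 0.05 with siSCD#1 (adjusted p = 1.03e-12), and 5.97 ± 0.61 against 10.12 ± 0.06 with siSCD#2 (-4.15 ± 0.16, adjusted p = 1.3e-15). The 3 IGR37 siSCD#2 libraries had SCD at 6.52, 5.32 and 6.09, a wider spread than any other group. The SE of 0.16 is shared by all groups of the first table, so it is too small for this group and too large for groups with less spread. The inhibitor acts on the enzyme, so the transcript does not check exposure to it. SCD was 9.72 ± 0.07 with the inhibitor and 9.43 ± 0.09 with DMSO in 501mel (0.29 ± 0.16, adjusted p = 0.573), and rose in IGR37 to 10.36 ± 0.06 from 9.74 ± 0.02 (0.63 ± 0.16, adjusted p = 0.00215). In 501mel the 3 SCDi libraries (9.65, 9.73 and 9.79) all lay above the 3 DMSO ones (9.47, 9.33 and 9.50). The adjusted p of 0.573 therefore does not show that SCD was unchanged.

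**Figure D1:**
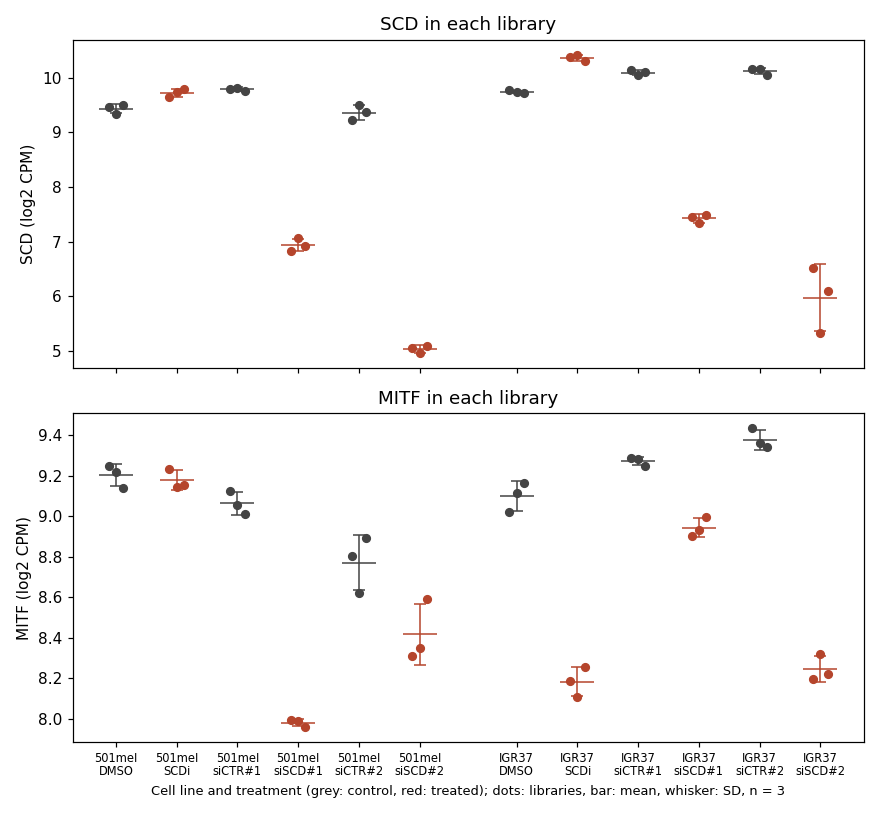
SCD and MITF level in each library. Points are log2 CPM of single libraries of the 12 groups, with mean ± SD, n = 3 per group. The 2 tables were normalised separately, so levels compare only within a table.

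In 501mel the SCD inhibitor raised stress genes driven by ATF4 and genes of cholesterol synthesis, while few other genes moved. ATF4 (ENSG00000128272.14, chromosome 22), the transcription factor of the amino acid response, rose to 9.38 ± 0.11 from 8.69 ± 0.10 (0.69 ± 0.14, adjusted p = 0.0188). SESN2 (1.45 ± 0.15, adjusted p = 1.55e-05), an inhibitor of mTORC1, NUPR1 (1.51 ± 0.23) and the glutathione-degrading CHAC1 (1.16 ± 0.24, adjusted p = 0.0271) rose with it. MITF (ENSG00000187098.15, chromosome 3) was unchanged at -0.02 ± 0.08 (adjusted p = 0.978). In all, 31 genes rose and 8 fell of 13364, with 1311 at an unadjusted p under 0.05, and 14 rises and 1 fall were at least 2-fold.

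Of the 35 genes of the PERK-ATF4 amino acid response, 9 rose and none of the others fell past the threshold (19 rose adjusted over the list alone), with a median change of 0.36 (camera adjusted p = 3.06e-23). Of 25 cholesterol synthesis and uptake genes 3 rose (10 adjusted over the list alone, median 0.33, adjusted p = 2.27e-13), among them INSIG1 by 0.68 ± 0.10 and HMGCS1 by 0.72 ± 0.13. Other rises were TSC22D3 (1.21 ± 0.19), DDIT4 (0.93 ± 0.16), the early response gene EGR1 (0.89 ± 0.18), the secreted stress factor GDF15 (0.69 ± 0.08, adjusted p = 6.05e-05) and the lipid phosphatase LPIN1 (0.83 ± 0.15). Falls among genes at or above the median level were small, with the chromatin protein RCC1 (-0.47 ± 0.09), ZMYM3 (-0.46 ± 0.10), the flavin kinase RFK (-0.46 ± 0.10) and the ubiquitin ligase RNF145 (-0.42 ± 0.07). The desaturase FADS1 rose by 0.45 ± 0.10 (adjusted p = 0.0426), the only one of 19 fatty acid synthesis genes past the threshold.

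The hypoxia and glycolysis list of 27 genes moved up as a whole (median 0.16, camera adjusted p = 0.00866) with 2 rises adjusted over the list alone. Over all genes 0 of its members passed in limma, with 5 higher and 1 lower at an unadjusted p under 0.05. Ribosomal proteins, whose reads are shared with pseudogene copies, rose as a list (median 0.20, adjusted p = 1.19e-09), G2 and mitosis genes fell (median -0.09, adjusted p = 0.0412) and dedifferentiated and invasive melanoma genes rose (median 0.31, adjusted p = 0.00643). These 3 did not pass with an estimated correlation, where adjusted p was 0.104, 0.104 and 0.0717. Reads of NT5E, a surface marker in the last list, were 14 against 0 (at least 4.47-fold). AXL (ENSG00000167601.11, chromosome 19), a receptor of invasive melanoma, had 11 and 14 reads (adjusted p = 0.967). The 9 measured LXR targets had a median of 0.38, with 0 past the threshold in limma and 3 higher at an unadjusted p under 0.05. Interferon genes had a median of 0.03 and a mean of -0.09, and none of the MITF, fibroblast or NRF2 lists was called.

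Many of these calls depended on the choice of libraries. With only the 6 libraries compared, 8 genes passed, and ATF4 (adjusted p = 0.0848, 0.000308 to 0.107 over the alternatives), SESN2 (0.0848, from 3.51e-07) and NUPR1 (0.0742, from 3.29e-06) did not, while INSIG1 (0.0223) and GDF15 (0.0338) did. Leaving out a library gave 17 genes (without SCDi replicate 3) to 31, and ATF4 reached an adjusted p of 0.151.

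In IGR37 the inhibitor set off a broad stress response, with falls of MITF and of genes for pigment and DNA replication. ATF4 rose to 10.05 ± 0.02 from 7.58 ± 0.17 (2.47 ± 0.14, adjusted p = 3.01e-13). The cystine carrier SLC7A11 (4.36 ± 0.16), asparagine synthetase ASNS (4.34 ± 0.16) and the stress factor DDIT3 (4.15 ± 0.15, adjusted p = 5.26e-17) rose with it. MITF fell to 8.18 ± 0.07 from 9.10 ± 0.07 (-0.92 ± 0.08, adjusted p = 9.74e-10), while AXL stayed at 9 against 6 reads (adjusted p = 0.977). In all, 2797 genes rose and 3093 fell, of which 1136 and 791 at least 2-fold.

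Lists of the unfolded protein response rose. Of 35 PERK-ATF4 genes 31 rose and 2 fell (the same adjusted over the list alone), with a median of 1.83 (camera adjusted p = 1.84e-25). Of 23 IRE1-XBP1 and ATF6 genes 20 rose and 1 fell (the same over the list alone, median 1.04, adjusted p = 3.49e-13), among them HERPUD1 (3.37 ± 0.08), the chaperone HSPA5 (2.07 ± 0.09) and XBP1 (1.61 ± 0.08). NF-kB and inflammatory genes followed with 14 up and 1 down of 23 (the same over the list alone, adjusted p = 7.04e-07), led by RELB at 3.42 ± 0.20. NRF2 genes counted 14 up and 1 down of 19 (the same over the list alone, adjusted p = 6.06e-07), with the glutathione enzyme GCLM at 2.12 ± 0.10. Of 19 p53 and cell death genes 8 rose and 2 fell (the same over the list alone, adjusted p = 0.025), with the BH3-only gene BBC3 at 3.08 ± 0.17 and the death receptor TNFRSF10B at 1.67 ± 0.14. JUN rose by 3.47 ± 0.12, SESN2 by 3.49 ± 0.15, CHAC1 by 3.43 ± 0.24 and VEGFA by 2.34 ± 0.13.

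Of 30 MITF and pigment cell genes 20 fell and 1 rose (20 and 2 over the list alone), with a median of -0.50 (adjusted p = 1.74e-08): the tyrosinase TYR (-1.10 ± 0.09), the channel TRPM1 (-2.00 ± 0.17) and the carrier SLC45A2 (-1.03 ± 0.09). Of 28 DNA replication genes 27 fell (27 over the list alone, adjusted p = 3.89e-18), with RRM2 at -1.73 ± 0.07, MCM4 at -1.65 ± 0.08 and TYMS at -1.50 ± 0.10. G2 and mitosis genes counted 17 down and 1 up of 28 (19 and 1 over the list alone, median -0.33, adjusted p = 0.000261) and BIRC5 at -0.70 ± 0.08. Of 29 oxidative phosphorylation genes 14 fell (14 over the list alone, adjusted p = 1.76e-06), with ATP5G1 at -1.63 ± 0.10, and of 16 heat shock genes 10 fell and 2 rose (11 and 3 over the list alone, adjusted p = 0.00162), with HSPA8 at -1.90 ± 0.13. Large falls included PI15 (-3.15 ± 0.12), the PI3-kinase subunit PIK3R3 (-2.78 ± 0.13), ID1 (-2.59 ± 0.15), MARCKSL1 (-2.56 ± 0.09) and the kinetochore gene ZWINT (-2.11 ± 0.13).

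Ribosomal proteins counted 11 up and 1 down of 32 and MAPK output 8 up and 1 down of 20 (both the same over the list alone, both camera adjusted p = 0.0285), with adjusted p of 0.516 and 0.176 with an estimated correlation. Lipid lists were mixed. Fatty acid synthesis had 5 up and 7 down of 19 (median -0.22, mean 0.12), cholesterol 10 up and 6 down of 25 (adjusted p = 0.84), and lipid droplet genes 3 up and 6 down of 23. Fibroblast markers fell in 4 of 7, LUM by 1.91 ± 0.32.

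**Figure D2:**
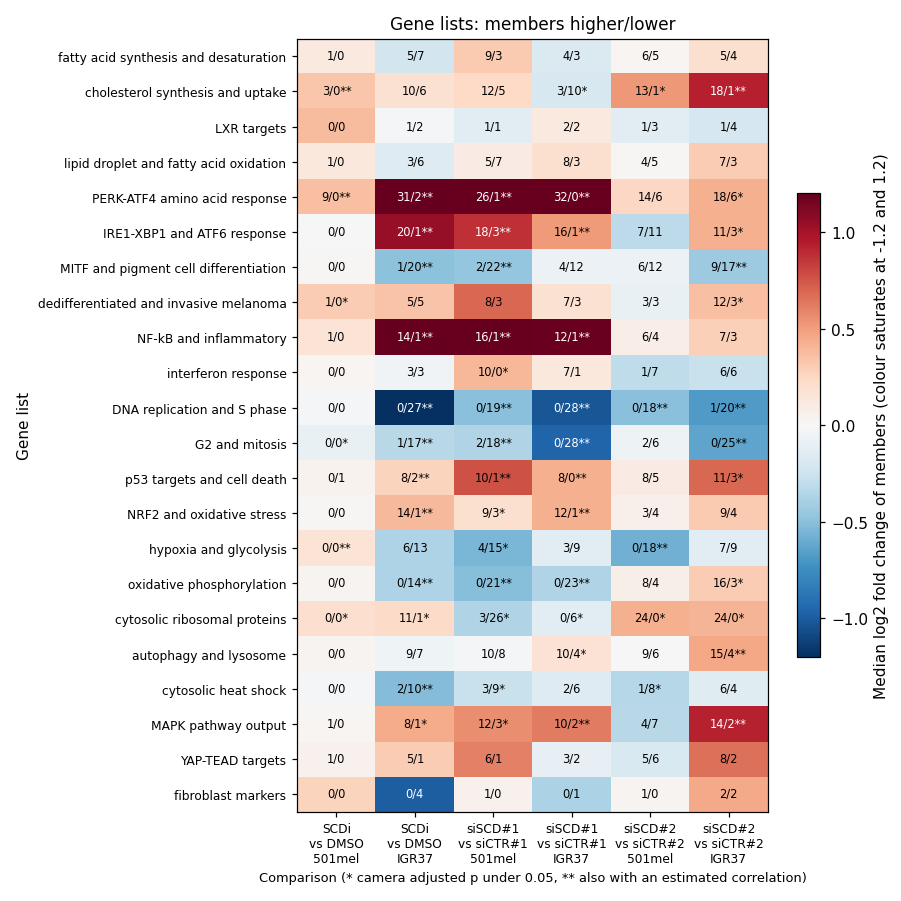
Gene lists in the 6 treatment comparisons. Colour gives the median log2 fold change of the list, saturating at -1.2 and 1.2. Text gives members higher and lower past the threshold, and asterisks mark lists called by camera, with a second asterisk where the call holds with an estimated correlation.

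In 501mel siSCD#1 raised stress and inflammatory genes and lowered MITF. MITF fell to 7.98 ± 0.02 from 9.06 ± 0.06 (-1.08 ± 0.06, adjusted p = 1.37e-09). Its 3' untranslated region holds the 7-base word GCTTCCT, whose genes fell most with this siRNA in both lines. The word is held by 18.9% of genes scored in 501mel. ATF4 rose by 1.07 ± 0.09 (adjusted p = 1.65e-07) and its targets CHAC1 (3.57 ± 0.23), DDIT3 (3.39 ± 0.11) and SESN2 (3.16 ± 0.12) rose with it. In all, 2733 genes rose and 2881 fell of 13066, of which 1047 and 625 at least 2-fold. AXL had 36 reads with siSCD#1 and 39 with siCTR#1, whose libraries were deeper. Its levels were 1.71 ± 0.71 and 1.10 ± 0.91 log2 CPM (limma adjusted p = 0.372).

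Of 35 PERK-ATF4 genes 26 rose and 1 fell (28 and 2 over the list alone, median 1.26, camera adjusted p = 4.02e-17), and of 22 IRE1-XBP1 and ATF6 genes 18 rose and 3 fell (the same over the list alone, adjusted p = 4.58e-09), with the cochaperone DNAJB9 at 3.04 ± 0.16. NF-kB genes counted 16 up and 1 down of 24 (20 and 1 over the list alone, adjusted p = 2.51e-07), with the chemokine CXCL8 at 821 against 24 reads (5.63 ± 0.24). Of 19 p53 and cell death genes 10 rose and 1 fell (10 and 2 over the list alone, adjusted p = 0.00092), with GADD45A at 2.90 ± 0.22, PMAIP1 at 1.97 ± 0.19 and BBC3 at 1.88 ± 0.11. Further rises were the fatty acid binder FABP7 (3.17 ± 0.27), GTPBP2 (3.23 ± 0.62) and the autophagy receptor SQSTM1 (1.34 ± 0.07).

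Of 30 MITF and pigment cell genes 22 fell and 2 rose (22 and 3 over the list alone, median -0.47, adjusted p = 6.12e-08), with TRPM1 at -1.95 ± 0.11 and SLC45A2 at -1.06 ± 0.07. DNA replication genes fell in 19 of 28 (20 down and 1 up over the list alone, adjusted p = 2.24e-07), with E2F1 at -1.39 ± 0.11 and RRM2 at -1.05 ± 0.08. G2 and mitosis genes fell in 18 with 2 up of 28 (20 and 2 over the list alone, adjusted p = 0.0002), with AURKA at -1.02 ± 0.10. Oxidative phosphorylation genes fell in 21 of 29 (22 over the list alone, adjusted p = 4.02e-09), with ATP5G1 at -1.49 ± 0.10. Large falls included the aldo-keto reductase AKR7A2 (-3.27 ± 0.11), the replication gene GINS1 (-3.11 ± 0.12), MYLK3 (-2.57 ± 0.22) and TPGS2 (-2.52 ± 0.16). Of these AKR7A2, MYLK3 and TPGS2 hold the word GCTTCCT, as do E2F1, SQSTM1 and PHLDA1, and GINS1 holds CTTCCTA, another word whose genes fell with siSCD#1 (z of -7.76 in 501mel and -6.21 in IGR37).

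Of the lists called by camera, 6 did not pass with an estimated correlation. Ribosomal proteins fell in 26 and rose in 3 of 32 (the same over the list alone, adjusted p = 2.24e-07, and adjusted p = 0.0794 with an estimated correlation), with RPL5 at -0.77 ± 0.06. Hypoxia and glycolysis genes fell in 15 and rose in 4 of 27 (16 and 5 over the list alone, 0.00121 and 0.150), with the lactate dehydrogenase LDHA at -1.14 ± 0.08. MAPK output genes rose in 12 and fell in 3 of 20 (13 and 3 over the list alone, 0.00342 and 0.0512), with PHLDA1 at 1.21 ± 0.06 and ETV5 at -0.92 ± 0.07. NRF2 genes rose in 9 and fell in 3 of 19 (the same over the list alone, 0.0267 and 0.0794), heat shock genes fell in 9 and rose in 3 of 16 (the same over the list alone, 0.0262 and 0.0794). Interferon genes rose in 10 of 26 (8 over the list alone, 0.0488 and 0.149), with BST2 at 1.60 ± 0.25. Fatty acid synthesis (9 up, 3 down of 19), cholesterol (12 up, 5 down of 25) and dedifferentiated melanoma genes (8 up, 3 down of 29) were not called. LXR targets had a median of -0.13 and a mean of 0.03, and autophagy genes a median of -0.02 while camera ranked them up.

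In IGR37 siSCD#1 raised stress genes and lowered every measured gene of the DNA replication and mitosis lists, with a small fall of MITF. ATF4 rose by 1.81 ± 0.09 (adjusted p = 6.51e-10), CHAC1 by 4.02 ± 0.23, SESN2 by 3.95 ± 0.12, RELB by 3.91 ± 0.18 and DDIT3 by 3.65 ± 0.11. MITF fell to 8.94 ± 0.05 from 9.27 ± 0.02 (-0.33 ± 0.06, adjusted p = 0.000402) and holds the word GCTTCCT. AXL had 22 against 56 reads, at levels of 0.67 ± 0.77 against 1.55 ± 0.26 log2 CPM (limma adjusted p = 0.205). In all, 2181 genes rose and 2534 fell, of which 607 and 581 at least 2-fold.

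Of 35 PERK-ATF4 genes 32 rose (32 over the list alone, median 1.40, camera adjusted p = 2.13e-27), with the pseudokinase TRIB3 at 2.61 ± 0.08. Of 22 IRE1-XBP1 and ATF6 genes 16 rose and 1 fell (16 and 2 over the list alone, adjusted p = 6.12e-10), with DNAJB9 at 3.22 ± 0.16, HERPUD1 at 3.05 ± 0.12 and XBP1 at 2.20 ± 0.08. NF-kB genes counted 12 up and 1 down of 24 (the same over the list alone, adjusted p = 1.76e-07), NRF2 genes 12 up and 1 down of 19 (the same over the list alone, adjusted p = 1.5e-06), and p53 and cell death genes 8 up of 19 (8 over the list alone, adjusted p = 0.00177), with BBC3 at 2.28 ± 0.11. MAPK output counted 10 up and 2 down of 20 (the same over the list alone, adjusted p = 0.000571), with EGR1 at 1.94 ± 0.22.

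All 28 DNA replication genes fell (median -1.02, adjusted p = 2.3e-19), with MCM4 at -1.36 ± 0.08, as did all 28 G2 and mitosis genes (median -0.96, adjusted p = 2.35e-19), with CDK1 at -1.19 ± 0.09 and BIRC5 at -1.12 ± 0.07. Oxidative phosphorylation genes fell in 23 of 29 (23 over the list alone, adjusted p = 4.69e-09). Large falls included GINS1 (-2.28 ± 0.12), AKR7A2 (-2.27 ± 0.11), TPGS2 (-1.92 ± 0.16) and ARL6IP1 (-1.83 ± 0.11), of which GINS1 and ARL6IP1 hold CTTCCTA and the others GCTTCCT. GCTTCCT is held by 19.1% of genes scored in IGR37, 23.4% of those lower and 17.5% of those higher past the threshold. CTTCCTA is held by 846 of 6196. Cholesterol genes fell in 10 and rose in 3 of 25 (the same over the list alone), with the sterol oxidase MSMO1 at -1.35 ± 0.11 (camera adjusted p = 0.028, and adjusted p = 0.126 with an estimated correlation). Ribosomal proteins (6 down of 32, 5 over the list alone, 0.015 and 0.432) and autophagy genes (10 up, 4 down of 27, the same over the list alone, 0.033 and 0.0639) were lost in the same way, with GABARAPL1 at 1.91 ± 0.09. Of 30 MITF and pigment cell genes 12 fell and 4 rose (13 and 4 over the list alone), and the list was not called (adjusted p = 0.139). YAP-TEAD targets had a median of -0.10 with camera ranking them up. The interferon gene IFIT1, which holds the word GCTTCCT, had 0 against 24 reads (at least 4.93-fold lower).

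**Figure D3:**
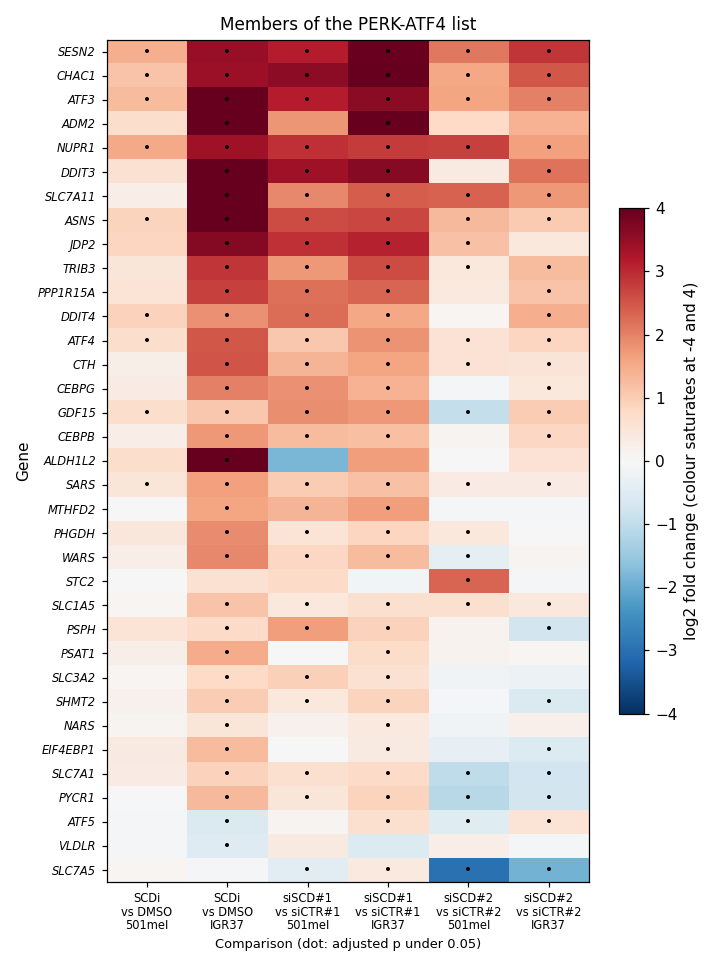
Log2 fold change of the 35 measured genes of the PERK-ATF4 amino acid response in the 6 treatment comparisons. Dots mark adjusted p under 0.05 in limma, n = 3 libraries per group.

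In 501mel siSCD#2 lowered glycolysis and DNA replication genes and changed stress genes in both directions. MITF fell by 0.35 ± 0.08 (adjusted p = 0.001; 0.0509 with only the groups compared and 0.000461 to 0.0509 over the alternatives). ATF4 rose by 0.58 ± 0.14 (adjusted p = 0.00159), with NUPR1 at 2.73 ± 0.23, SLC7A11 at 2.35 ± 0.16 and SESN2 at 2.12 ± 0.15. The amino acid carrier SLC7A5, on the same PERK-ATF4 list, fell by 2.97 ± 0.14. In all, 2447 genes rose and 2612 fell of 13364, of which 628 and 884 at least 2-fold. AXL had 10 and 14 reads (adjusted p = 0.973).

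Hypoxia and glycolysis genes fell in 18 of 27 (18 down and 1 up over the list alone, median -0.57, camera adjusted p = 4.91e-08), with the enolase ENO2 at -2.35 ± 0.15, BNIP3 at -1.23 ± 0.10 and the glucose carrier SLC2A3 at -1.13 ± 0.11. DNA replication genes fell in 18 of 28 (19 over the list alone, median -0.50, adjusted p = 7.05e-08), with GINS1 at -2.27 ± 0.14 and E2F1 at -1.58 ± 0.13. Cholesterol genes rose in 13 and fell in 1 of 25 (14 and 2 over the list alone), with HMGCS1 at 1.43 ± 0.13 and INSIG1 at 1.03 ± 0.10 (adjusted p = 0.000111, and adjusted p = 0.132 with an estimated correlation). Ribosomal proteins rose in 24 of 32 (24 over the list alone, 1.52e-08 and 0.147), with RPL13 at 1.10 ± 0.11, and heat shock genes fell in 8 and rose in 1 of 16 (the same over the list alone, 0.044 and 0.132), with HSPD1 at -0.51 ± 0.07. PERK-ATF4 genes counted 14 up and 6 down of 35 (16 and 6 over the list alone, adjusted p = 0.164) and IRE1-XBP1 and ATF6 genes 7 up and 11 down of 23 (7 and 12 over the list alone, adjusted p = 0.181), with the disulfide isomerase PDIA3 at -2.17 ± 0.10. Neither list was called.

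Beside SCD, large falls included the lipid kinase PIP4K2C (-3.19 ± 0.14), the purine enzyme IMPDH1 (-3.16 ± 0.14), the peroxidase PRDX3 (-3.09 ± 0.14) and the neurofilament NEFL (-2.83 ± 0.15), and further rises were PNRC1 (2.25 ± 0.18), ZBTB41 (2.20 ± 0.17) and MAP2 (1.97 ± 0.13). PRDX3 and MDM2 (-1.25 ± 0.11) hold the 7-base word TCTGATC, whose genes fell most with siSCD#2 in both lines, and so do SLC7A11 and RPL13, which rose. Among genes scored in 501mel 9.2% hold TCTGATC, with 12.8% of those lower and 8.0% of those higher past the threshold. MITF and IMPDH1 do not hold it, but hold TCACCAC, another word whose genes fell with siSCD#2 (z of -6.57 in 501mel and -5.31 in IGR37). TCACCAC is held by 687 of 6331 genes scored in 501mel. Of 30 MITF and pigment cell genes 6 rose and 12 fell, and of 29 oxidative phosphorylation genes 8 rose and 4 fell, with neither list called. Fatty acid synthesis genes had a median of 0.03 and a mean of -0.33, lipid droplet genes 0.01 and -0.01, and autophagy genes a median near 0 and a mean of 0.10. The fatty acid mean includes SCD, the silenced target, which pulls it down. The phospholipid enzyme LPCAT3 fell by 1.53 ± 0.19 and LPIN1 rose by 1.42 ± 0.15.

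In IGR37 siSCD#2 lowered MITF, raised cholesterol and MAPK output genes and lowered cell cycle genes. MITF fell to 8.25 ± 0.06 from 9.38 ± 0.05 (-1.13 ± 0.08, adjusted p = 2.45e-11). ATF4 rose by 0.87 ± 0.14 (adjusted p = 1.22e-05), DDIT3 by 2.16 ± 0.15 and SESN2 by 2.85 ± 0.15. AXL had 6 against 0 reads (at least 2.32-fold only if the 6 reads are taken as exact), and did not pass (limma adjusted p = 0.0788). A rise of AXL is not established by so few reads. In all, 3101 genes rose and 3035 fell, of which 956 and 1231 at least 2-fold. The replicates of this group differed most, with a chi-square per degree of freedom of 10.0 to 28.6 against 1.94 to 6.91 in every other group. The spread is shared with the other groups, so SEs and adjusted p given for this comparison can be too small and its counts of calls too high.

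Of 25 cholesterol genes 18 rose and 1 fell (the same over the list alone, median 0.94, camera adjusted p = 2.71e-08), among them HMGCS1 by 2.26 ± 0.13 and INSIG1 by 1.39 ± 0.10. MAPK output rose in 14 and fell in 2 of 20 (the same over the list alone, median 0.92, adjusted p = 4.23e-05), with EGR1 at 2.95 ± 0.18, SPRY2 at 2.30 ± 0.17 and the phosphatase DUSP6 at 1.96 ± 0.12. Autophagy and lysosome genes rose in 15 and fell in 4 of 27 (the same over the list alone, adjusted p = 0.00223), with GABARAPL1 at 1.49 ± 0.11. Of 30 MITF and pigment cell genes 17 fell and 9 rose (18 and 9 over the list alone, median -0.43, adjusted p = 0.00223), with the coactivator PPARGC1A at -2.55 ± 0.16, the receptor MET at -1.76 ± 0.08 and TYRP1 at -1.37 ± 0.07. DNA replication genes fell in 20 and rose in 1 of 28 (21 and 1 over the list alone, adjusted p = 7.71e-09), with E2F1 at -2.33 ± 0.13, and G2 and mitosis genes fell in 25 of 28 (26 over the list alone, adjusted p = 1.23e-10), with BIRC5 at -1.54 ± 0.08. Large rises included DNAJB9 (3.51 ± 0.18), the cadherin CDH19 (3.48 ± 0.18), SESN3 (3.17 ± 0.18) and TFAP2C (2.91 ± 0.17), and large falls beside SCD the nucleoside carrier SLC29A1 (-2.96 ± 0.20), RIMS4 (-2.85 ± 0.17), the phosphatase PTPRF (-2.68 ± 0.18) and HMGA1 (-2.62 ± 0.15).

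A further 6 lists were called by camera and did not pass with an estimated correlation. PERK-ATF4 genes rose in 18 and fell in 6 of 35 (19 and 7 over the list alone, median 0.43, adjusted p = 0.00223, and adjusted p = 0.263 with an estimated correlation). IRE1-XBP1 and ATF6 genes rose in 11 and fell in 3 of 23 (11 and 4 over the list alone, 0.00289 and 0.137), and ribosomal proteins rose in 24 of 32 (24 up and 1 down over the list alone, 6.81e-07 and 0.137). Dedifferentiated and invasive melanoma genes rose in 12 and fell in 3 of 29 (13 and 3 over the list alone, 0.0441 and 0.137), with fibronectin FN1 at 1.62 ± 0.10. Cell death genes rose in 11 and fell in 3 of 19 (12 and 3 over the list alone, 0.0441 and 0.0796), with BMF at 2.78 ± 0.29, and oxidative phosphorylation genes rose in 16 and fell in 3 of 29 (the same over the list alone, 0.0279 and 0.274). NF-kB genes were not called (7 up, 3 down of 23, adjusted p = 0.0504), although PTGS2, the inducible cyclooxygenase, had 179 against 0 reads (at least 69.3-fold). Median and mean differed in sign for fatty acid synthesis (0.20 and -0.23), hypoxia (-0.14 and 0.06) and heat shock genes (-0.14 and 0.03). The fatty acid list includes SCD, the silenced target, which pulls its mean down. Of 4 epithelial markers 1 rose and 1 fell, and of 3 blood and endothelial markers CD68 fell by 1.72 ± 0.19.

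Under DMSO IGR37 and 501mel differed in many genes, among them most of the dedifferentiated and invasive melanoma list. MITF did not differ past the threshold there (-0.10 ± 0.08, adjusted p = 0.276), while under siCTR#2 it was 9.38 ± 0.05 in IGR37 and 8.77 ± 0.14 in 501mel (not tested). Under DMSO ATF4 was lower in IGR37 (-1.11 ± 0.14, adjusted p = 1.6e-07), and SCD (0.31 ± 0.16, adjusted p = 0.0962) did not differ past the threshold. Of 29 dedifferentiated and invasive melanoma genes 22 were higher in IGR37 and 4 lower (the same over the list alone, median 2.14, camera adjusted p = 0.000499). AXL, also on that list, was near the floor in both lines, at -1.99 ± 2.15 in IGR37 and -0.33 ± 0.85 in 501mel. Higher were the surface genes CD9 (7.39 ± 0.35), CSPG4 (6.40 ± 0.26) and CD44 (6.26 ± 0.27), with S100A6 (6.88 ± 0.29). Lower were the testis antigens MAGEA4 (-7.66 ± 0.41) and CTAG2 (-7.30 ± 0.32) and the melanosome receptor GPR143 (-7.09 ± 0.31). In all, 4158 genes were higher and 3968 lower in IGR37, 60.8% of those tested. SCD passed in 5 other settings, with an adjusted p of 0.00172 when only the groups compared were fitted and 0.000423 to 0.424 over the alternatives.

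A further 5 lists had a camera adjusted p of 0.035 and did not pass with an estimated correlation. Higher in IGR37 were lipid droplet and fatty acid oxidation genes (16 up, 4 down of 23), hypoxia and glycolysis genes (16 up, 5 down of 27) and autophagy genes (16 up, 4 down of 27), each with adjusted p = 0.0676 there. Lower were DNA replication genes (16 down, 4 up of 28, adjusted p = 0.190) and ribosomal proteins (18 down, 6 up of 32, 19 and 6 over the list alone, adjusted p = 0.596).

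The effect of the inhibitor differed between the lines in stress genes, pigment genes and DNA replication. The difference (IGR37 minus 501mel) was -0.89 ± 0.11 for MITF (adjusted p = 1.78e-06), 1.78 ± 0.19 for ATF4 (adjusted p = 1.86e-07) and 0.33 ± 0.22 for SCD (adjusted p = 0.291). It was large for SLC7A11 (4.09 ± 0.22), DDIT3 (3.55 ± 0.21) and RELB (3.48 ± 0.28), and negative for PI15 (-3.09 ± 0.17), PIK3R3 (-2.85 ± 0.18) and ATAD3B (-2.58 ± 0.41). In all, 1642 genes differed upward and 2049 downward. Of 35 PERK-ATF4 genes 30 differed upward (30 over the list alone, adjusted p = 3.89e-23), as did 19 of 23 IRE1-XBP1 and ATF6 genes with 1 downward (the same over the list alone, adjusted p = 1.48e-15). MITF and pigment genes differed downward in 19 of 30 (19 over the list alone, adjusted p = 2.34e-09) and DNA replication genes in 27 of 28 (27 over the list alone, adjusted p = 2.14e-20). NF-kB, p53 and NRF2 lists were called upward, and G2, hypoxia, oxidative phosphorylation and heat shock lists downward. Cholesterol genes (1 up, 8 down of 25, the same over the list alone, adjusted p = 0.0367) did not pass with an estimated correlation (adjusted p = 0.254).

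For siSCD#1 the difference had the opposite sign for MITF, at 0.75 ± 0.08 (adjusted p = 4.52e-05): MITF fell more in 501mel. It was 0.74 ± 0.13 for ATF4 (adjusted p = 0.00112) and 0.19 ± 0.10 for SCD (adjusted p = 0.213). RELB (2.13 ± 0.25), TNFAIP3 (1.87 ± 0.15) and IQCE (1.79 ± 0.12) differed upward, and GTPBP2 (-3.97 ± 0.88), ATXN2L (-3.49 ± 0.56) and RABGGTB (-3.20 ± 0.63) downward. In all, 1313 genes differed upward and 1342 downward. MITF and pigment genes differed upward in 17 and downward in 2 of 30 (18 and 3 over the list alone, adjusted p = 3.35e-07). DNA replication genes differed downward in 13 and upward in 2 of 28 (17 and 2 over the list alone), G2 and mitosis genes downward in 19 of 28 (22 over the list alone), and cholesterol genes downward in 10 of 25 (11 over the list alone, adjusted p = 0.000214). PERK-ATF4 genes (7 up, 3 down of 35, adjusted p = 0.0124) and ribosomal proteins (16 up, 1 down of 32, adjusted p = 0.00016) did not pass with an estimated correlation (adjusted p = 0.308 and 0.261), nor did the fatty acid, NRF2 and hypoxia lists (0.0681, 0.0534 and 0.318). With quantile normalisation the ribosomal proteins turned downward (adjusted p = 0.262). Centring libraries on their median shifted all genes by about 0.108 here and moved the share of upward calls from 49.5 to 64.5%.

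For siSCD#2 MITF again fell more in IGR37 (-0.78 ± 0.11, adjusted p = 1.88e-05), while ATF4 (0.29 ± 0.19, adjusted p = 0.314) and SCD (0.18 ± 0.22, adjusted p = 0.616) did not pass. These 2 changed with the choice of libraries: without IGR37 siSCD#2 replicate 2 ATF4 differed by 0.52 (adjusted p = 0.0103) and SCD by 0.51 (adjusted p = 0.00391), and with library weights by 0.60 and 0.69 (adjusted p = 0.0021 and 0.00141). Without replicate 1 SCD differed by -0.09. Among those upward were SLC2A3 (3.25 ± 0.15), the cyclin CCND1 (2.53 ± 0.25) and IER3 (2.38 ± 0.15), and FBXO17 (-2.06 ± 0.30) and C19orf70 (-2.09 ± 0.44) were downward. In all, 1553 genes differed upward and 1266 downward. IRE1-XBP1 and ATF6 genes differed upward in 17 of 23 (17 over the list alone, adjusted p = 3.21e-09), MAPK output in 12 of 20 (12 and 1 downward over the list alone, adjusted p = 1.2e-07) and hypoxia and glycolysis genes in 11 of 27 (13 and 1 downward over the list alone, adjusted p = 1.04e-06). G2 and mitosis genes differed downward in 20 of 28 (21 over the list alone, adjusted p = 2.5e-11) and MITF and pigment genes in 13, with 2 upward, of 30 (13 and 3 over the list alone, adjusted p = 0.000527). Autophagy genes were called upward (adjusted p = 0.0347), but not with quantile normalisation or the stricter filter. Cholesterol, dedifferentiated melanoma, heat shock and YAP-TEAD genes were called upward only without an estimated correlation, with adjusted p of 0.136, 0.0773, 0.0922 and 0.0773 with it.

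In 501mel 13 genes rose and 1 fell in all 3, against 1.22 and 0.360 expected of independent lists. With only the groups compared 2 genes rose in all 3, and of those named next only IL21R was called with the inhibitor (adjusted p = 0.0223). NUPR1 (1.51, 2.91 and 2.73 with the inhibitor, siSCD#1 and siSCD#2), SESN2 (1.45, 3.16 and 2.12), ATF3 (1.26, 3.14 and 1.58) and ASNS (0.88, 2.61 and 1.30) rose, as did the cytokine receptor IL21R (18 against 0 reads with the inhibitor, at least 5.75-fold), and the shared fall was RNF145 (-0.42, -1.14 and -0.51). In IGR37 675 genes rose and 785 fell in all 3, against 109 and 140 expected. CXCL8 (4.54, 3.56 and 3.49) and DNAJB9 (2.38, 3.22 and 3.51) rose, and the replication genes GINS1 (-1.89, -2.28 and -2.29) and POLE2 (-1.55, -1.76 and -1.55), with SOX9 (-3.11, -1.45 and -2.71) and the proteoglycan CSPG5 (-1.75, -1.90 and -1.64), fell.

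In all 6 comparisons 11 genes rose, against 0.0103 expected of independent lists: ATF4, ATF3, SESN2, CHAC1, ASNS, NUPR1, SARS, EGR1, A2M, AKNA and IL21R. Comparisons within a table share the spread of each gene, so their lists are not independent and the expected count can be too low. With only the groups compared 1 remained, IL21R, and other settings gave 8 to 13. Replicate blocks dropped ATF4, ATF3 and SARS from the set, and voom dropped ATF3, A2M and IL21R, so no gene stayed in every setting. A2M, a protease inhibitor, rose by 0.79, 0.83 and 1.24 in 501mel and by 1.39, 1.41 and 1.84 in IGR37. By limma 0 genes fell in all 6, where only 8 falls passed with the inhibitor in 501mel. At an unadjusted p under 0.05, 65 genes were higher and 52 lower in all 6 (0.539 and 0.643 expected of independent lists). The 11 rises and 0 falls therefore do not show that shared changes are only rises. Across genes, log2 fold changes of the inhibitor and siSCD#1 correlated at 0.681 in IGR37 and 0.098 in 501mel, and those of the 2 siRNAs at 0.406 and 0.316. Each reagent correlated with itself in the other line at 0.607 for siSCD#1 and 0.625 for siSCD#2, and the inhibitor at 0.291. Of genes called with both siRNAs, 79.3% in IGR37 and 73.5% in 501mel changed in the same direction, and both siRNAs raised 396 and lowered 474 genes in both lines (20.1 and 26.4 expected).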

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

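Chosen after the results were seen were the tests of the separate tables and of all low words, of the libraries that widen the spread, of depth, of exchanged samples and swapped tubes, and of the splits behind the differences between lines. The other tests below were set out before the values they measure were seen. No explanation below is a finding, since each pattern was found and tested on the same libraries.

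The effects differed between the lines for 3691 genes with the inhibitor, 2655 with siSCD#1 and 2819 with siSCD#2. With the inhibitor the difference (IGR37 minus 501mel) was -0.89 for MITF, 1.78 for ATF4, 4.09 for SLC7A11, 3.55 for DDIT3, 3.48 for RELB, 3.47 for ASNS and 3.08 for JUN. On the other side stood PI15 (-3.09), PIK3R3 (-2.85), ATAD3B (-2.58), MARCKSL1 (-2.28) and the cochaperone SGTA (-2.26). With siSCD#1 it was 0.75 for MITF, 0.74 for ATF4, 2.13 for RELB, 1.87 for the NF-kB inhibitor TNFAIP3, 1.79 for IQCE, 1.77 for the Notch ligand DNER and 1.76 for SLC37A2. Downward were GTPBP2 (-3.97), FABP7 (-3.73), ATXN2L (-3.49), RABGGTB (-3.20) and EEF1A1 (-2.94). With siSCD#2 it was -0.78 for MITF, 3.25 for SLC2A3, 2.53 for CCND1, 2.38 for IER3, 2.34 for FOXC1 and 2.33 for the chromatin protein HMGA2. Downward were the small RNAs SNAR-C4 (-2.80), SNAR-C3 (-2.52) and SNAR-E (-2.20), with C19orf70 (-2.09) and FBXO17 (-2.06). SNAR genes and EEF1A1 have near copies that share reads, so their values are uncertain.

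A first pattern was the small response of 501mel to the inhibitor, with 39 genes against 5890 in IGR37. Without the IGR37 siSCD#2 libraries, which widen the spread of the table, 98 genes passed in 501mel, far below the IGR37 count. The 501mel libraries held more reads than the IGR37 ones (median 114% of theirs), which argues against depth; thinning, set out first, removed too few reads to test it. Spike-in levels separated the labels DMSO and SCDi in 501mel by 2.55 on the log2 scale, which argues against tubes swapped after spike-ins were added, and the highest other split called 2 genes, which argues against some samples exchanged earlier (a full exchange would leave the count as it is). Less inhibition of 501mel at the same dose was not tested, and a lower need for SCD stays open: siSCD#1 and siSCD#2 changed 5614 and 5059 genes there (4715 and 6136 in IGR37), with PERK-ATF4 medians of 1.26 and 0.25 (1.40 and 0.43), but off-target silencing could add to these.

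A second pattern was that the 2 siRNAs changed different genes, with a correlation across genes of 0.406 in IGR37 against 0.607 for siSCD#1 between the lines. Genes whose 3' untranslated region holds GCTTCCT fell most with siSCD#1 (z of -10.60 in 501mel and -7.92 in IGR37), and those with TCTGATC with siSCD#2 (-8.02 and -5.76), so off-target silencing through the siRNA seed may account for part of the difference. The test had asked for a z under -8 in each line, which IGR37 missed; that bound was too strict, since 120 shuffles reached no lower than -5.22 and planted words were found in 6 of 6 runs. The correlation was 0.413 without genes holding either word. It was 0.441 without those holding any word below the lowest shuffle, which left 2547 of 6448 genes. Both stayed below 0.607, but that value includes genes holding the words. The test also covered only annotated 3' untranslated regions and no silencing by the control siRNAs. It therefore cannot exclude direct silencing as the whole cause, and effects downstream of silenced genes stay open. The inhibitor correlated with siSCD#1 from another table at 0.681 and with siSCD#2 from its own at 0.282 in IGR37, which argues against separate tables there, but at 0.098 and 0.203 in 501mel, where separate tables stay open.

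Another pattern was the spread of the IGR37 siSCD#2 libraries. The shallowest held 80.6% of the table's median gene reads, which argues against low depth, and all 3 lay nearest to the mean of the other 2, which argues against a library of another group under this label. Unequal strength of the response could not be settled: the median size of the correlation between deviation and effect was 0.337, between the bounds set for and against it. A first version of this test, leaving each library out, gave a biased value and was replaced. No biological explanation was tested.

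The spike-ins were not the same in treated and control libraries. Past the threshold in limma were 16 of 47 for the inhibitor in 501mel and 26 of 47 in IGR37, 35 and 31 of 45 for siSCD#1, and 41 and 35 of 47 for siSCD#2. The pattern was shared, with correlations of 0.966 to 0.985 between comparisons and 11 to 15 spike-ins lower in the treated libraries. Use of 2 spike-in mixes, 1 for treated and 1 for control libraries, could give such a pattern and the gap of 2.55, and was not tested. No gene was scaled on spike-ins. Reads on the Mitf-FLAG sequence were 2 to 25 per library, with 25 in IGR37 siSCD#2 replicate 1 and 3 and 7 in the others of that group.

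For each treatment comparison 10 splits of 6 libraries exist, too few for a share under 0.05. The real splits gave 39, 5890, 5614, 4715, 5059 and 6136 genes and the highest others 2, 2, 5, 2, 4 and 3, in the order inhibitor, siSCD#1 and siSCD#2 with 501mel first in each, so 1 of 10 reached the real count. For the lines under DMSO it was 8126 against 0. For the differences between lines, splits were first made within each line, where 11, 2 and 7 of 100 gave as many genes (highest others 4519, 6373 and 6891), all of them keeping or mirroring the labels of a line. This showed the structure of the effects and not chance, so residuals of a model without the difference were dealt instead. Only the real arrangement, 1 of 100, reached the real count each time (highest others 745, 820 and 1754). That argues against chance spread between these libraries. Differences between cultures were not tested by it, since the labels do not say whether replicates were separate cultures.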

How the results depend on the processing

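Voom, library weights, the fit without the IGR37 siSCD#2 libraries, and shared calls with only the groups compared or with voom were tests chosen after the results were seen. Tests of the recovered reads by edgeR and DESeq2 were planned but not run. The deposited values are log2 values, but the recovered reads would have allowed these tests. Dropping the filter removed no gene and tested nothing.

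The inhibitor in 501mel was the least stable result. Its 39 genes became 8 with only the groups compared (7 up, 1 down, 3 of them among the 39), 152 with library weights and 98 without the IGR37 siSCD#2 libraries. Leaving out a library gave 17 (SCDi replicate 3) to 31 (DMSO replicate 1), with 18 without SCDi replicate 2. The share of rises went from 79.5% to 67.8% with library weights. SCD there (0.292) had an adjusted p of 0.0438 without the IGR37 siSCD#2 libraries, and 0.0438 to 0.681 over the alternatives. The SD of SCD was 0.61 in the IGR37 siSCD#2 group and at most 0.13 in the other groups of the first table, which widened its shared SE. What else moved the adjusted p was not tested. Voom gave 27, 6390, 5855, 5363, 5214 and 6696 genes for the inhibitor, siSCD#1 and siSCD#2, with 501mel first in each. The siSCD#2 difference between lines fell to 1821 genes with only the groups compared. Shared calls in 501mel were 9 at an adjusted p under 0.01 and 2 with only the groups compared, against 14. In IGR37 they were 891 at an adjusted p under 0.01 and 783 with a log2 change of at least 0.5, against 1460. Over settings other than leaving out a library, 4071 checks of named genes gave the same call, 74 lost it, 33 gained it and 3 moved in value; leaving out a library, 2810, 94, 4 and 8 did, with most of these losses in the inhibitor comparison in 501mel. No named gene changed direction with its call.

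Among lists, 3 changed direction in a setting. With fry, fatty acid synthesis in IGR37 with siSCD#2 was down (adjusted p = 0.00331), as was the NF-kB difference with siSCD#1 (adjusted p = 0.00294). The fatty acid list includes SCD, the target of the siRNA, and was not tested without it. With quantile normalisation the ribosomal protein difference with siSCD#1 turned down (adjusted p = 0.262). Over all comparisons replicate numbers paired the libraries poorly: of 17 pairs 5 correlated above 0.1 (-0.192 to 0.252) and 7 were best with their own number. For the inhibitor in 501mel every pair was best with its own number (0.034, 0.252 and 0.18), so pairing there stays possible. With replicate blocks 6064 genes passed for the inhibitor in IGR37, 4443 for siSCD#1 in IGR37, and 5200 and 4918 for siSCD#2 in 501mel and IGR37.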

Other observations

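The hypotheses below were tests chosen after the results were seen, apart from the shared calls and the line comparison, which were planned.

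IGR37 and 501mel started from different states. Under DMSO the protease inhibitor TIMP3 (6.50 ± 0.27), the proteoglycan CSPG4 (6.40 ± 0.26) and the linker histone H1F0 (6.61 ± 0.39) were higher in IGR37, and FSCN1 (-6.78 ± 0.25), SMPD4 (-6.68 ± 0.26) and GPM6A (-6.65 ± 0.40) were lower. ATF4 was lower in IGR37 under DMSO (7.58 ± 0.17 against 8.69 ± 0.10) and siCTR#1 (7.86 ± 0.02 against 8.76 ± 0.14, not tested) but level under siCTR#2 (8.15 ± 0.12 against 8.19 ± 0.15, not tested), and rose more in IGR37 with the inhibitor and with siSCD#1. MITF was 9.38 ± 0.05 in IGR37 and 8.77 ± 0.14 in 501mel under siCTR#2, and 9.27 ± 0.02 and 9.06 ± 0.06 under siCTR#1, so the lines did not stand at 1 MITF level in all controls. MITF fell in 5 of 6 comparisons without a rise of AXL past the threshold in any of them, and reads of AXL were too few in both lines to rule out a small rise. SOX9 and MITF fell together in IGR37 with all 3 perturbations.

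A hypothesis is that loss of SCD activity raises part of the ATF4 program in both lines, and that other changes depend on the line and the reagent. The 11 genes that rose in all 6 comparisons include ATF4, ATF3, ASNS, SESN2 and CHAC1, beside IL21R, AKNA, A2M and EGR1 from outside that list, which is consistent with it. Against it, the PERK-ATF4 list was not called with siSCD#2 in 501mel (14 up, 6 down, adjusted p = 0.164), and its call with siSCD#2 in IGR37 was lost with an estimated correlation (adjusted p = 0.263). Of the 11 genes, ATF4 and ATF3 dropped out with replicate blocks, and ATF3 also with quantile normalisation and with voom. For 501mel the inhibitor calls rest on few genes: with only the groups compared 8 passed, and 1 gene rose in all 6, so this part may not hold. Lowering SCD with another siRNA, or adding oleate to inhibited cells, would test it.

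A further hypothesis is that the fall of MITF with the siRNAs may be partly off-target. The 3' untranslated region of MITF holds GCTTCCT, the word with the lowest z for siSCD#1, and TCACCAC, a low word for siSCD#2. The weakest lowest word had a z of -5.76. GCTTCCT is held by 18.9% of the genes scored in 501mel and TCACCAC by 687 of 6331, so holding them says little about MITF alone. MITF does not hold TCTGATC, the word with the lowest z for siSCD#2, so TCACCAC was picked from several low words. Only 2547 of 6448 genes compared in IGR37 were found to hold no low word of either siRNA, so a match of this kind was likely for any gene. The mean difference for GCTTCCT was -0.197 in 501mel and -0.133 in IGR37, and for TCACCAC -0.143 and -0.133. These word effects differ little between the lines beside the differences of 0.75 and -0.78 for MITF, which therefore do not settle the hypothesis. Off-target silencing does not account for the inhibitor, which lowered MITF by 0.92 in IGR37. An SCD cDNA resistant to each siRNA would separate these effects.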
